A study of Mus musculus with 12 samples.

How the data were processed

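The data were 12 two-colour spotted cDNA arrays of mouse keratinocyte RNA, 6 per calcium level. Total RNA was labelled with Cy3 or Cy5 by a Genisphere kit, per the labels' protocols. The deposited values are log2 ratios of the 2 dyes of each array; the log base is not stated and was taken as log2 from the range of the values (-7.88 to 4.60). The scanner, background correction, normalisation and spot filter are not given in the sources used here. The deposited array medians lay between -0.0005 and 0.0005, so the values were already centred; which dye was the numerator is not stated.

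Probes were named from the platform annotation: 7457 had 1 gene symbol, 481 had several and 1620 were unlisted and are unnamed here. Of the single symbols 7368 were updated through their gene ID with a mouse annotation table (GRCm38.p6). Probes of 1 symbol were averaged into 6774 genes, of which 623 had more than 1 probe, and the other probes were kept as 2101 unnamed rows, 8875 rows in all. Trp53, Krt1, Krt14 and Ivl were not among the named genes of these arrays.

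Each array was centred on its median. The value of a dye-swap pair was the difference of its forward and reversed values divided by 2. Dye bias cancels in it only where both arrays carry it in equal size. A pair with a value on only 1 array was missing. Both calcium levels were fitted together as 3 + 3 pairs with limma 3.58.1 (R 4.3.3, lmFit and eBayes). A row was tested at a calcium level where at least 2 pairs of that level had a value. For the difference at least 2 pairs of each level were needed. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Every adjusted p of a gene in the text is limma's. Rows had a median of 2 residual degrees of freedom, and eBayes added 9.55 prior degrees of freedom.

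The orientation departs from the plan. The rule fixed before the data were examined kept the deposited signs if forward and reversed arrays of a level had a median correlation above 0.1, unless the Trp63 probe changed sign by more than its spread. The correlations were 0.446 (low) and 0.255 (high), and the Trp63 probe was -0.89 ± 0.61 (SD, n = 5) on forward and 0.02 ± 1.31 (SD, n = 4) on reversed arrays, so the rule would have kept the signs. It was set aside after the data were seen. The component shared by both orientations repeated between pairs in 59 genes of other organs (lens, liver, pancreas, testis and others; median r = 0.716, range 0.406 to 0.921) more than in 47 genes of the keratinocyte lists (0.494). The component that flips with the dye repeated in the keratinocyte genes (0.683, range 0.437 to 0.913) more than in genes of other organs (0.359). A ratio already turned would show the reverse. The genes of other organs were chosen after the data were seen, and the keratinocyte genes belong to lists that the report describes. The labels list deltaNp63alpha as the second channel of every array, the reversed ones included. A deposited ratio of second over first channel would already be turned, which favours the kept signs. The kept-sign reading is given as an alternative.

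The 27 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01) on rows complete in all pairs, which left 15 lists of 3 to 8 members, with fry beside it; fry called none. Counts of called members are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time: Trp63 and the focus genes Trp53, Trp73, Serpinb5, Cdkn1a, Krt1, Krt10, Krt5, Krt14, Ivl, Lor and Flg; the 8 largest rises and 8 largest falls per level among called genes with the same sign in every pair; up to 3 genes of smallest p per list with a called member; and for the difference, where none passed, the 3 smallest p in each direction. Genes outside the rule are marked or are list members that passed when adjusted over the list alone.

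The procedure was tested on simulated pairs over 10 seeds, with gene spreads drawn from the prior of the real fit and the same in all pairs. Both arrays of a simulated pair carried the same dye bias, which cancels, so unequal dye bias was not tested. Changed genes were planted only among rows with at least 2 pairs at both levels, so recovery in the other rows was not measured. In the low calcium comparison (4646 rows) it recovered a median of 17% (12% to 32%) of 50 genes changed by 0.5 on the log2 scale, 92% (80% to 98%) at 1, and 100% at 2 and at 3. In the high calcium comparison (7263 rows) it recovered 16% (8% to 36%), 88% (76% to 98%), 100% and 100%. False calls were a median of 9.28% (3.31% to 16.8%) and 8.59% (3.18% to 16.7%) of all calls, above the 5% aimed at. These shares depend on the number of changed genes planted, which was the same at both levels. This noise model replaced one whose spread (prior SD 0.138, against 0.278 in the real fit) was too small, after its result was seen. That one recovered 74% and 64% at 0.5, 98% and 99% at 1, with 7.08% and 1.66% false calls.

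The alternatives were no centring, arrays on the same spread, arrays in place of pairs with a dye term (with and without a random pair block), the repeat number as a block, each level alone, pairs with 1 array kept, rows complete on all arrays, single probes, a trended and robust variance, an adjusted p under 0.10, a log2 size of at least 0.58, the kept-sign orientation, each orientation alone, and each pair left out. Chosen after the data were seen were centring on the probes complete on all arrays, the array set (well filled or sparse) as a block, removal of residual dye bias by regression, the well-filled pairs alone, and list tests on all genes tested.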

Results

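Primary skin keratinocytes of C57Bl/6NCr mice were transduced with adenovirus encoding deltaNp63alpha, the p63 isoform that lacks the N-terminal transactivation domain, or beta-galactosidase as the control. RNA was collected 41 h after transduction. Cells were kept for 24 h in 0.05 mM calcium (low calcium) or in 0.12 mM calcium (high calcium), which induces keratinocyte differentiation per the labels. Each of 12 spotted cDNA arrays held both RNAs of 1 calcium level, one labelled with Cy3 and the other with Cy5. Each calcium level had 3 repeats, each hybridised once with deltaNp63alpha in Cy5 (forward) and once with deltaNp63alpha in Cy3 (reversed). The 2 arrays of a repeat formed a dye-swap pair and counted as 1 replicate. The labels call the arrays technical repeats, so p-values may measure only technical spread. No array compared calcium levels directly, so the effect of calcium itself was not measured. Of 9558 probes, 3366 to 9096 had a value on an array. Low calcium repeat 1 and high calcium repeats 1 and 2 were well filled, and low calcium repeats 2 and 3 and high calcium repeat 3 were sparse. The number of arrays limits the precision.

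**Figure D1:**
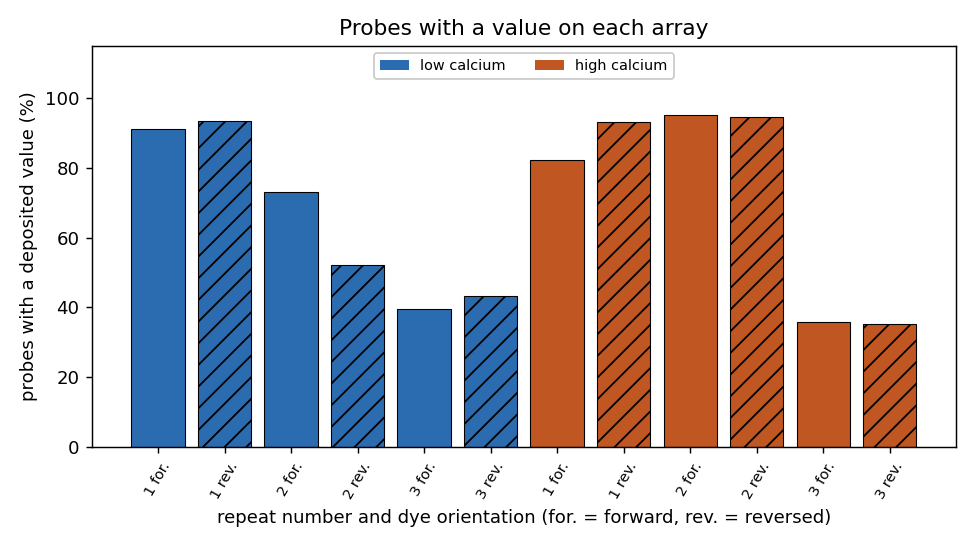
Percent of the 9558 probes with a deposited value (y axis) on each array (x axis), by repeat and dye orientation; colour gives the calcium level and hatching the reversed arrays. The low calcium repeat 3 and high calcium repeat 3 arrays lie between 35.2% and 43.3%, and both low calcium repeat 1 arrays lie above 91%.

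All signs below rest on a choice. The labels list deltaNp63alpha as the second channel of every array, so a ratio of second over first channel would need no turning. The deposited values were read as Cy5 over Cy3, so the reversed arrays were turned. A rule fixed before the data were examined would have left them as deposited, and that reading called 763 genes in low calcium and 0 in high calcium (limma; 1270 at an unadjusted p under 0.05). Under that reading 3 of the 19 rows called here in low calcium and 52 of the 101 called in high calcium kept their direction. The overall direction is likely, not settled: it rests on the usual order of a dye ratio and on the series title, which names maspin as negatively regulated. The direction of maspin (Serpinb5) is therefore not independent evidence, and all signs would turn together under the opposite order. The targeted gene did not back the direction chosen. The single Trp63 probe was not called higher in the RNA labelled deltaNp63alpha. In low calcium its log2 ratio was -0.16 ± 0.25 (SE, n = 2 pairs, limma adjusted p = 0.919). The pairs there had opposite signs, -0.78 in repeat 1 and 0.45 in the sparse repeat 2. In high calcium it was -0.55 ± 0.25 (SE, n = 2 pairs, limma adjusted p = 0.446), from the well-filled pairs at -0.59 and -0.51. Under the alternatives other than the kept-sign orientation, Trp63 ranged from -0.99 to 0.67 in low calcium and from -0.94 to 0.0666 in high calcium. Whether this probe detects the transgene is not known here. If it does, the negative pair values would go against the direction chosen.

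The first comparison asked what deltaNp63alpha changed in low calcium. Prl2c5, a member of the proliferin family, fell 4.92-fold (log2 -2.30 ± 0.18 SE, n = 3 pairs; limma adjusted p = 0.000152). It lacked complete pairs in high calcium and was not tested there. The forward arrays of high calcium repeats 1 and 2 read -2.03 and -2.13, so its fall was not shown to be confined to low calcium. Sprr1a, a precursor of the cornified envelope, fell 4.45-fold (log2 -2.15 ± 0.21 SE, n = 3 pairs; limma adjusted p = 0.000419). Serpinb2, an inhibitor of plasminogen activators, fell 2.65-fold (log2 -1.41 ± 0.17 SE, n = 3 pairs; limma adjusted p = 0.00376). In all, 19 of 4646 genes or unnamed rows passed the test; 18 fell and 1, an unnamed row, rose.

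Among the other named genes that fell were Trex2, an exonuclease (log2 -1.50, from pairs at -0.78 and -2.23), Sh3bp5l (-1.37), Itgb1, the beta-1 integrin subunit (-1.25), the proteoglycan gene Sdc1 (-1.22) and Crabp2, which encodes a retinoic acid binding protein (-1.18). Maspin itself, Serpinb5, had a log2 ratio of -0.80 ± 0.16 (SE, n = 3 pairs), lower in 3 of 3 pairs, and its limma adjusted p of 0.04998 lay at the threshold. The log2 ratio of Serpinb5 was -0.10 (limma adjusted p = 0.899) on forward arrays alone, which read -0.83, -0.04 and 0.56 in repeats 1 to 3, and -1.50 on reversed arrays alone. Thbs1, which encodes thrombospondin, fell by 1.10 on the log2 scale. Other falls also differed between orientations. On forward arrays alone Serpinb2 (-0.69), Crabp2 (-0.56), Itgb1 (-0.38), Sdc1 (-0.24) and Thbs1 (-0.24) did not pass (limma adjusted p from 0.168 to 0.769). On reversed arrays alone they were at -2.13, -1.64, -2.11, -2.20 and -1.96. Trex2 and Sh3bp5l had similar values in both orientations and passed in neither. Prl2c5 and Sprr1a passed in both. With 1 low calcium pair left out, the limma adjusted p of Serpinb5 was 0.210 (without repeat 1) and 0.160 (without repeat 3), that of Thbs1 0.205, 0.0551 and 0.0520 (without repeats 1, 2 and 3), that of Sh3bp5l 0.0903 and 0.0826 (without repeats 2 and 3) and that of Itgb1 0.0674 (without repeat 1). Filaggrin (Flg, -1.51; limma adjusted p = 0.191), Cdkn1a, the p21 inhibitor of cyclin-dependent kinases (-0.73; limma adjusted p = 0.194), Krt5 (-0.24, from pairs at -0.39 and -0.09), Trp73 (0.15) and Lor (0.00, or -0.0808 to 0.146 with 1 low calcium pair left out) did not pass. At the same log2 ratio, Flg in low calcium passed with 1 high calcium pair left out (limma adjusted p = 9.43e-09, 3.20e-09 and 0.0134 without repeats 1, 2 and 3). In the fits without repeats 1 and 2 the spread of Flg itself was ignored, since all genes shared 1 variance. Krt10 was measured in only 1 pair and was not tested.

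By list, 2 of 17 measured p53 family members and targets fell in low calcium (Thbs1 and Serpinb5), and 4 fell when adjusted over the list alone, with Cdkn1a and Plk2 (-0.76) added. With 1 array kept, Cdkn1a was at -0.42 and Plk2 at -0.41. Of 8 basal keratinocyte genes 2 fell, Itgb1 and Sdc1, as they did adjusted over the list alone; Cd44 (-0.48, or -0.19 without low calcium repeat 1 and -0.72 without repeat 3) did not pass. Of 7 serpins 2 fell, Serpinb2 and Serpinb5, likewise adjusted over the list alone, and Serpinf1 (0.58, from pairs at -0.09 and 1.26) did not pass; the list's median was 0.15 and its mean -0.14. Of 15 terminal differentiation genes Sprr1a alone fell, and 5 fell adjusted over the list alone; the median was 0.00 and the mean -0.37. Of 20 matrix, protease and migration genes 1 fell, Thbs1, also when adjusted over the list alone; Tnc (-0.53) and Tgfbi (-0.54, or -0.25 without low calcium repeat 1 and -0.89 without repeat 2) did not pass. Camera called this list lower over its 8 complete members (adjusted p = 0.0207). That call was lost with an estimated correlation (adjusted p = 0.928).

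The low calcium count was fragile: it was 6 without low calcium repeat 1, 50 without high calcium repeat 1, 51 without high calcium repeat 2 and 30 without high calcium repeat 3, and 0 with arrays on the same spread, with a trended and robust variance or with pairs that had 1 array kept. Without high calcium repeat 1 or 2 the prior degrees of freedom were infinite, so all genes shared 1 variance there. In simulated pairs a median of 9.28% of low calcium calls and 8.59% of high calcium calls were false. Those pairs held 50 changed genes at each log2 size, had the same spread and carried equal dye bias on both arrays. The share depends on how many genes change, so it does not give the false share among the real calls.

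The second comparison asked the same question in high calcium. Genes of the terminal differentiation list were among the largest falls with deltaNp63alpha, though camera did not call the list. Flg, the filament-aggregating protein of the granular layer, fell 3.80-fold (log2 -1.93 ± 0.40 SE, n = 3 pairs; limma adjusted p = 0.0351). Its log2 ratio was -1.07 with a limma adjusted p of 0.0993 without high calcium repeat 3, and its limma adjusted p was 0.0512 without low calcium repeat 2. Klk7 and Klk5, serine proteases of corneocyte shedding, fell 3.32-fold and 3.22-fold (log2 -1.73 ± 0.23 and -1.69 ± 0.27 SE, n = 2 pairs each). Krt10, a suprabasal keratin, fell 2.98-fold (log2 -1.57 ± 0.20 SE, n = 2 pairs; limma adjusted p = 0.00821). In all, 101 of 7263 rows passed; 61 fell, of which 53 had a gene name, and 40 rose, of which 8 had one.

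The other large falls were Defb1, a beta-defensin (log2 -1.66, n = 3 pairs), Sprr1a (-1.63), Serpinb2 (-1.57) and Il1f5, an antagonist of the interleukin-1 family (-1.45). Serpinb5 had a log2 ratio of -0.89 ± 0.19 (SE, n = 2 pairs; limma adjusted p = 0.0388), lower in 2 of 2 pairs. Cdkn1a fell 2.45-fold (log2 -1.29 ± 0.20 SE, n = 2 pairs; limma adjusted p = 0.0102). In repeat 3 each of these had a value on the forward array alone, which no pair value uses, and it was positive: 1.47 for Serpinb5 and 1.17 for Cdkn1a. With it kept, the log2 ratios were -0.0999 (limma adjusted p = 0.968) and -0.47 (limma adjusted p = 0.906). Serpinb5 was at -0.53 with arrays as replicates. Trp73 (0.26; limma adjusted p = 0.667), Krt5 (0.11, from pairs at -0.28 and 0.50) and Lor (-0.15, or -0.332 to 0.179 with 1 high calcium pair left out) did not pass. The named rises were Usp19 (1.88), Brip1os (1.63), A830082K12Rik (1.56), Exosc2 (1.33), Aven (1.31), Lima1 (1.29), Birc6 (1.13) and Nfic (1.01). Lima1 did not pass with the array set block (0.76, limma adjusted p = 0.329) or with the repeat number as a block (0.82, limma adjusted p = 0.217). Without high calcium repeat 3, Brip1os (1.12; limma adjusted p = 0.0538), Aven (1.20; limma adjusted p = 0.0807) and Birc6 (1.08; limma adjusted p = 0.0719) did not pass. The other 32 rises were unnamed rows. All 40 rises were also above 0 in low calcium repeat 1 (0.61 to 2.37), so in that repeat they were not particular to high calcium. Low calcium repeats 2 and 3 measured 10 and 7 of them, at 0.30 to 0.92 and at -0.10 to 1.31. In repeat 3 Birc6 (-0.10) and Aven (0.03) did not rise.

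**Figure D2:**
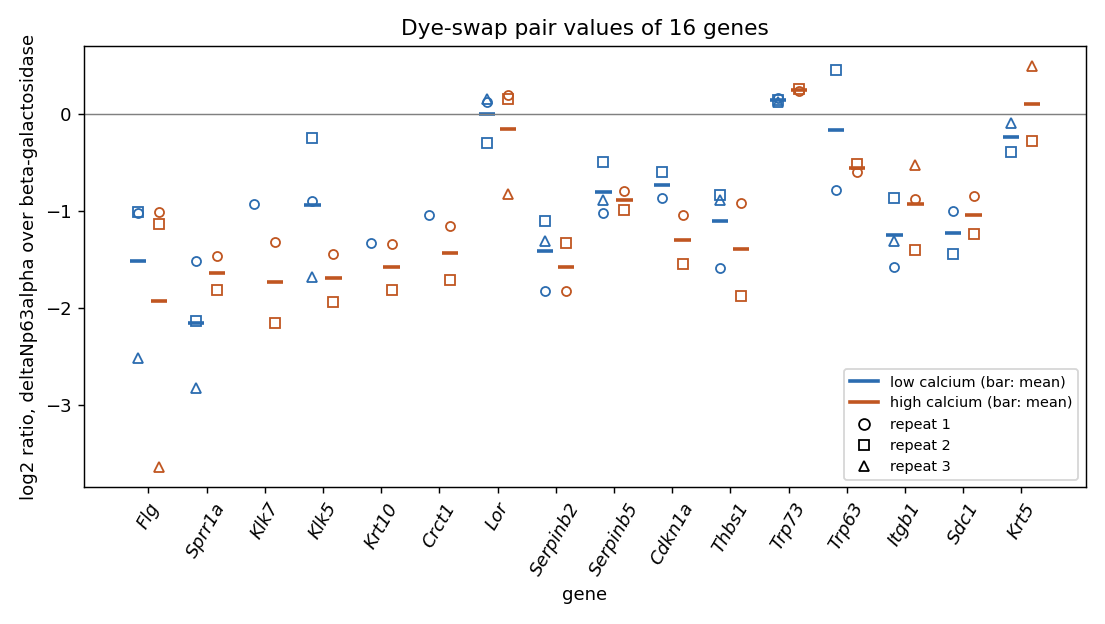
Log2 ratio of deltaNp63alpha over beta-galactosidase (y axis) of 16 genes (x axis); each symbol is 1 dye-swap pair, its shape the repeat, its colour the calcium level, and a bar the mean of at least 2 pairs. Every measured pair of Flg, Sprr1a, Serpinb2, Serpinb5, Itgb1 and Sdc1 lies below 0, and the Flg mean in high calcium (-1.93) is drawn down by 1 pair at -3.63.

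By list, 6 of 20 terminal differentiation genes fell in high calcium (Flg, Klk7, Klk5, Sprr1a, Krt10 and Crct1, the last by 1.43 on the log2 scale), and 8 fell adjusted over the list alone. Krt10 and Klk7 had a pair value only in repeat 1 of low calcium, at -1.32 and -0.93, so they could not be tested there. The counts of the 2 levels therefore cover different genes. Of 25 p53 family members and targets 3 fell, Thbs1 (-1.39, from pairs at -0.91 and -1.88), Cdkn1a and Serpinb5, and 10 fell adjusted over the list alone, among them Gadd45a (-0.93, from pairs at -0.38 and -1.48), Gadd45b (-0.77) and Mdm2 (-0.51). Thbs1 too had a positive value on the forward array alone in repeat 3 (1.05), and with it kept its log2 ratio was -0.58 (limma adjusted p = 0.878). Of 14 basal keratinocyte genes 2 fell, Sdc1 (-1.04) and Itgb1 (-0.93; -0.69 with a limma adjusted p of 0.275 without high calcium repeat 2), also adjusted over the list alone, and Tfap2c (0.49) did not pass; the median of the list was 0.04 and its mean -0.12. Of 10 serpins 2 fell, Serpinb2 and Serpinb5, also adjusted over the list alone; Serping1 (-1.08) did not pass. The value of Serping1 rested on high calcium repeat 3: it was -0.0144 without that repeat, and it passed at -1.48 (limma adjusted p = 6.99e-06) without repeat 1 and at -1.76 (limma adjusted p = 6.28e-09) without repeat 2, with 1 variance shared by all genes. In repeat 3 its forward array read -7.36 and its reversed array 0.91 after turning, so these values rest on 1 array that the other array of the pair contradicts. Of 32 genes of mitosis 1 fell, Ube2c (-1.06), a ubiquitin-conjugating enzyme of the anaphase-promoting complex, also adjusted over the list alone, and Smc4 (0.50) and Cdca3 (0.39, from pairs at 0.64 and 0.15) did not pass. Of 27 inflammatory genes 1 fell, Il33 (-1.16), also adjusted over the list alone. With the array set block Il33 was at -0.71 and did not pass (limma adjusted p = 0.280). S100a9 (-0.66) and Il18 (-0.62, or -0.32 without high calcium repeat 3) did not pass. Of 23 matrix, protease and migration genes Thbs1 alone fell, and 3 fell adjusted over the list alone; Col4a1 (-0.75) and Tnc (-0.63) did not pass over all genes, though Tnc passed at -0.89 (limma adjusted p = 0.0290) without high calcium repeat 3. Camera called no list in high calcium; the smallest adjusted p was that of terminal differentiation (0.182, over 4 complete members).

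**Figure D3:**
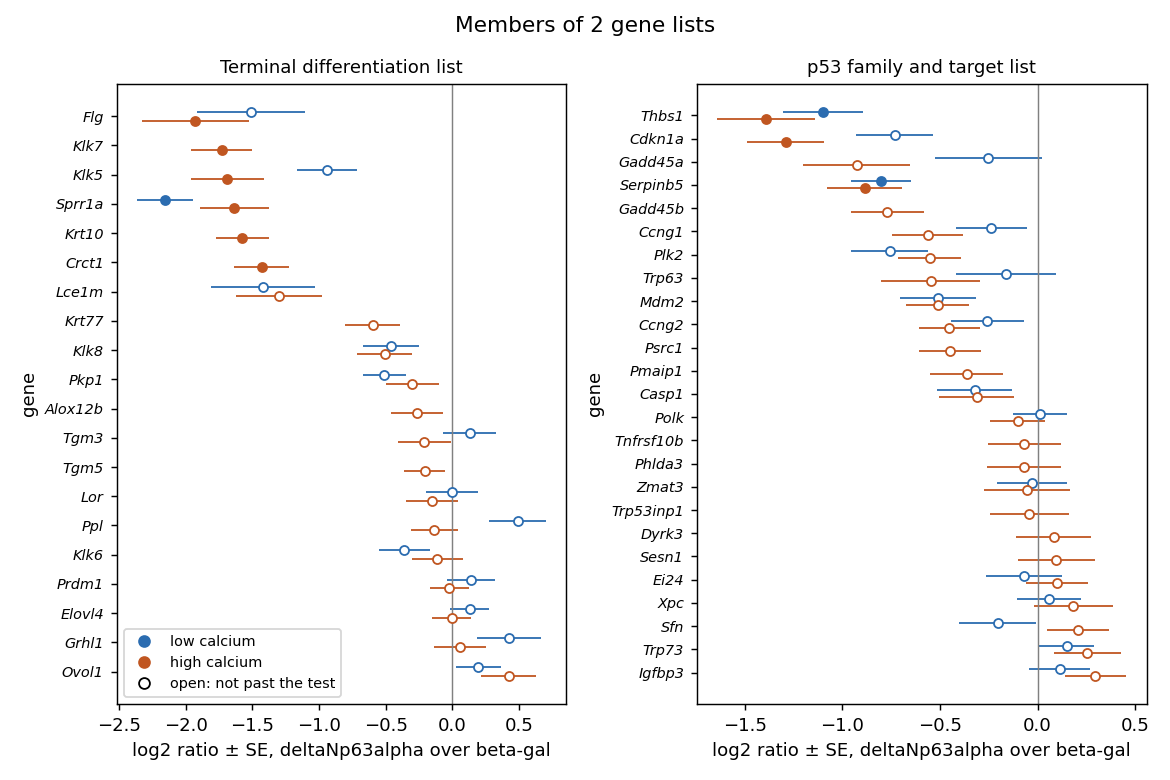
Log2 ratio of deltaNp63alpha over beta-galactosidase with its SE (x axis) for the tested members (y axis) of the terminal differentiation list and the p53 family and target list; colour gives the calcium level and filled symbols passed the test. In high calcium 6 differentiation genes and 3 genes of the p53 list are filled, all below 0.

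The high calcium count was 33 without high calcium repeat 1 and 34 without high calcium repeat 2, where fewer rows could be tested, and 1 with arrays on the same spread and 0 with a trended and robust variance or with pairs that had 1 array kept. The fits without repeat 1 or 2 again gave all genes 1 shared variance.

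The third comparison asked whether the effect of deltaNp63alpha differed between calcium levels. No gene passed (limma; 0 of 4209 rows, 107 at an unadjusted p under 0.05, smallest adjusted p = 0.858). The smallest p-values, none past the test, were those of Il33 (high minus low -1.59), Manba (-1.30) and Jcad (-0.96) among negative differences, and of Krt32 (0.94), Odf2l (0.91) and Rab34 (0.93) among positive ones. Without high calcium repeat 1 or without repeat 2, 1 gene passed, Serping1, named after its values were seen. Its value in high calcium repeat 3 was -3.23, which rests on the forward array named above, against -0.29 and 0.26 in the other pairs. A missed threshold does not show that the effects were equal.

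Of the 4209 rows tested at both levels, 17 were called in low calcium, 45 in high calcium and 11 in both. The rest of the 101 rows called in high calcium had too few low calcium pairs to be tested there. Of these 11, 10 fell and 1 rose. Independent lists would share 0.129 falling rows. The lists are not independent, since both levels came from 1 fit that shares the variance of each row. The figure of 0.129 is therefore no test of the overlap. The named shared genes were Sprr1a, Serpinb2, Serpinb5, Thbs1, Itgb1, Sdc1, Cav1, Anxa1 and Nktr, the last 3 named after their values were seen. All 17 rows called in low calcium had the same sign in high calcium, and 42 of the 45 called in high calcium had the same sign in low calcium. Across genes, which are not independent replicates, the log2 ratios of the 2 levels had a Pearson correlation of 0.50 and a Spearman correlation of 0.35. The Pearson value turned to -0.50 when forward arrays of 1 level were set against reversed arrays of the other. In that comparison the component shared by both orientations enters with opposite signs.

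Of 27 lists, 20 had no member past the test over all genes at either level. These included all 7 lists of markers of other cell types. Adjusted over the list alone, some members of these 20 lists passed. In low calcium these were 2 interferon response genes with higher values, Tap1 (1.01) and Ifit1 (0.61), 1 higher and 1 lower gene of the NRF2 list, 2 lower hair follicle genes, and 1 lower gene each of the cholesterol synthesis and muscle lists. In high calcium these were 1 higher gene of cholesterol synthesis, 3 lower genes of the Wnt list, 2 lower hair follicle genes, and 1 lower gene each of the Notch, EGF receptor, heat shock, fibroblast and sebaceous and adipose lists.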

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

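With the kept-sign orientation, 16 of the 19 rows called in low calcium and 49 of the 101 called in high calcium turned. Under the other alternatives, 404 of the 654 values of 33 named results past the test stayed past it. Most of the 654 could not turn, since the setting leaves the estimate as it is or the gene has 1 sign in every pair; 205 could, and all 205 kept their direction, but 28 of the 654 moved by over 1.5 times, 18 of them among the 66 from 1 orientation alone. Over 30 named results not past the test, 24 of 573 values turned and 30 passed, among them Flg, Klk5, Serping1 and Tnc with 1 pair left out. Among all rows called in high calcium, 1 turned with forward arrays alone and 3 with reversed arrays alone. Centring on the probes complete on all arrays, chosen after the data were seen, lowered the prior degrees of freedom from 9.55 to 3.92; 0 and 0 of the called 19 and 101 passed, with smallest adjusted p of 0.0603 and 0.0998, and 349 and 787 at an unadjusted p under 0.05. Signal over background was not given, so its limit was not assessed.

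For low and high calcium the counts, against 19 and 101, were 0 and 1 with arrays on the same spread (274 and 1051 unadjusted), 3 and 29 with arrays as replicates, 6 and 43 with a random pair block, 49 and 236 with each level alone, 0 and 0 with pairs of 1 array kept (512 and 555 unadjusted), 4 and 14 on rows complete on all arrays (1381 rows), 0 and 0 with a trended and robust variance (401 and 585 unadjusted; median prior degrees of freedom 19.6), 763 and 0 with the kept-sign orientation (1960 and 1270 unadjusted), 33 and 0 with forward arrays alone, 330 and 1 with reversed arrays alone, and 31 and 165 at an adjusted p under 0.10. Chosen after the data were seen, the array set block gave 47 and 134, residual dye removal 47 and 194, and the well-filled pairs alone 598 in high calcium. Leaving out 1 pair gave 6 to 51 in low calcium, 33 to 151 in high calcium and 0 to 1 for the difference. No centring (19 and 103), single probes (23 and 142) and a log2 size of at least 0.58 (19 and 101) stayed within 1.5 times. With the replicate block, without high calcium repeat 1 or 2 and, in low calcium, with each level alone, the prior degrees of freedom were infinite, so all genes shared 1 variance. The cause of the changes was not tested.

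With the repeat number as a block, 59 genes passed in low calcium, 117 in high calcium and 2 for the difference (Il33 and Serping1). Only 18 of the 59 and 59 of the 117 were among the 19 and 101 of the main fit. Of the 117, 19 rose and 98 fell. With the mean of each level removed, low and high calcium pairs of the same number correlated at -0.03, -0.11 and 0.20. Pairs of different numbers were not compared in this way, so whether the numbers pair the samples is not settled. The array set block gave 1 gene for the difference (Serping1); the other alternatives for the difference that kept all pairs gave 0.

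Against 1 called list, 0 were called with an estimated correlation, 2 with the replicate block, 0 to 6 with 1 pair left out and, chosen after the data were seen, 8 on all genes tested and 2 there with an estimated correlation. The cause was not tested.

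Named genes whose sign turned, outside the kept-sign orientation, had not passed the test. In low calcium these were Trp63 with the replicate block (0.17) and reversed arrays alone (0.67); with forward arrays alone Cdkn1a (0.13), Krt5 (1.15), Cd44 (0.23), Serpinf1 (-0.14) and Tnc (0.14); and Lor with reversed arrays alone (-0.38), with 1 pair left out (-0.0808 to 0.146) and centred on complete probes (-0.0337). In high calcium these were Trp63 with the array set block (0.0666); Trp73 with 1 array kept (-0.0834) and forward arrays alone (-0.0182); Krt5 on the same spread (-0.28), with arrays as replicates (-0.15), the random block (-0.12), the replicate block (-0.16), reversed arrays alone (-1.09) and residual dye removed (-0.0731); Lor with forward arrays alone (0.29), with 1 pair left out (-0.332 to 0.179) and on the well-filled pairs (0.18); and Serping1 with reversed arrays alone (0.41). The correlation across genes between levels, 0.50, was -0.50 for forward low against reversed high and -0.50 for the converse, and 0.86 over the 51 rows called at either level. Over the alternatives other than the kept-sign orientation, the printed list medians turned in 11 of 20 for differentiation in low calcium (-0.63 to 0.10), 4 of 19 for serpins in low calcium (-0.43 to 0.20), 9 of 21 for basal genes in high calcium (-0.33 to 0.25), and 1 of 20 in low (-0.00151 to 0.25) and 0 of 21 in high calcium (0.07 to 0.39) for DNA replication. Trp63 had 1 probe, so no alternative by probe was run.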

Other observations

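In high calcium, 21 of 26 tested DNA replication genes lay above 0 (median 0.14; 0.09 when centred on the probes complete on all arrays, with 8 below 0), though none passed the test alone. In low calcium 8 of 14 lay above 0 (median 0.06). A set test on the t values of all genes tested, chosen after the data were seen, called 8 list results. It called DNA replication higher in high calcium (adjusted p = 0.0288; adjusted p = 0.0169 with an estimated correlation), not in low calcium (adjusted p = 0.565). It called basal keratinocyte genes lower in low calcium (adjusted p = 0.000428; adjusted p = 0.000525 with an estimated correlation), not in high calcium (adjusted p = 0.685). The estimates came from 4 complete DNA replication genes (-0.211) and 3 complete basal genes (-0.00393). Both were negative and were set to 0 in the test. That lies below the preset correlation of 0.01, which lowers the p, so passing is no stricter test. These p-values were adjusted over 30 list results, against 52 with the preset correlation. Whether these differ between levels was not tested. The other calls were lost with an estimated correlation or had none. Terminal differentiation was lower in high calcium (adjusted p = 1.48e-10; 0.401 with an estimated correlation) and in low calcium (adjusted p = 0.00156; 0.694). The p53 list was lower in high calcium (adjusted p = 0.000278; 0.628) and in low calcium (adjusted p = 0.000217; 0.493). In low calcium, mitosis was higher (adjusted p = 0.0498; 0.419), and ribosomal proteins were lower (adjusted p = 0.0288), with too few complete members for an estimate. The largest DNA replication values in high calcium were Tyms (0.77, from pairs at 0.40 and 1.14) and Chaf1b (0.59), and Rrm1 was at -0.64, from pairs at -0.18 and -1.11. Further genes that fell in high calcium, named after their values were seen, were the tight junction gene Cldn1 (-1.33), the galectin Lgals3 (-1.01), the kinase inhibitor Cdkn2b (-0.95), Casp8 (-0.98) and the annexins Anxa1 (-1.23) and Anxa8 (-1.24).

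Of the tests below, that of residual dye bias in low calcium repeat 2 and those of other groupings were chosen before their results were seen, and the rest after.

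Much of the signal was shared by both dye orientations and is removed by the pair values where both arrays carry it in equal size. Dye bias is a candidate explanation: over genes of other organs the shared component correlated between pairs with a median r of 0.716. An effect of deltaNp63alpha would be expected to repeat best in keratinocyte genes, and the median r there was lower, by -0.222. The list of other organs was chosen after the data were seen, so this remains a hypothesis.

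Of the 40 rising rows in high calcium, 32 had no single gene name, against 8 of 61 falling rows (a 6.1-fold higher share, and 3.53-fold against the 22.6% of all tested rows; 2-sided Fisher's exact test over rows, which are not independent, p = 1.09e-11). All 40 were higher in high calcium repeat 1 (0.84 to 1.92) than in repeat 2 (0.31 to 1.18). All 40 were also above 0 in low calcium repeat 1 (0.61 to 2.37), and 31 were higher there than in high calcium repeat 1. Low calcium repeats 2 and 3 measured only 10 and 7 of them, at 0.30 to 0.92 and at -0.10 to 1.31. A candidate explanation is 1 abundant RNA species hybridising to many clones. The spread of the component shared by both orientations was 0.584 over rising rows relative to falling rows. This lay just inside a limit of 0.6 set after the data were seen. The spread of the values themselves in repeat 1 was nearer, 0.227 (SD) over rising and 0.281 over falling rows. Separate genes rising together stay open, since unnamed clones may be separate genes and their share was known when the test was framed.

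Low calcium repeat 2 correlated with the other pairs at a median r of -0.014 over all genes. Swapped labels within the pair would turn its sign, but over the keratinocyte lists the median r was 0.637. Its pair values correlated at -0.600 with the component shared by both orientations, against 0.071 to 0.296 in the other pairs. This correlation is set by the unequal spreads of the 2 arrays (SD 0.763 forward, 1.24 reversed). Noise on the wider array would give it as well as dye bias, so it does not show that dye bias stayed in the pair values. After the shared component was regressed out of the pair values, the median r was 0.101. This lay above the limit of 0.1 fixed beforehand by far less than the SD of 0.060 over the 5 other pairs. The regression uses the same shared component, so it cannot tell noise from dye bias either. Whether dye bias explains the low agreement stays open. No biological explanation was tested.

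The number of replicates is too small for other groupings to give a share under 0.05. For low calcium, 1 of 4 sign patterns of the pairs gave at least the real 19 calls, and the highest other gave 0. For high calcium, 1 of 4 gave at least the real 101, and the highest other gave 0. For the difference, all 10 splits of the pairs gave at least the real 0, and the highest other gave 0.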
